A study of Homo sapiens with 3 samples.

How the data were processed

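Anti-IRF3 ChIP-seq was done on BT549 cells carrying Cas9 with a control guide RNA, Smad3 guide 1 or Smad3 guide 2, delivered by lentivirus, and transfected with polyI:C. Fragment libraries were made with an Ion Xpress kit and amplified by PCR, per the labels' protocols. There were 3 groups with 1 library each, taken from the sample label that names the guide. Sample titles name BT549-caSmad3 cells for both Smad3 guides and BT549 for control, while the descriptions name BT549 for all, and which is right was not settled.

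The authors deposited 1 peak list per library, so peaks were called per library and not on pooled samples. Bowtie2 2.2.2.6, MACS2 2.1.0 and genome build hg38 are named, per the submitters' processing notes, without roles or settings. Whether an input library served as background for peak calling, and any filter on reads or duplicates, is not given in the sources used here. The lists hold positions and a score for each peak that the authors deposited without a stated scale. In each list the deposited scores were whole multiples of 1 step (0.663 in control, 0.512 in guide 1 and 0.479 in guide 2) for 99.9%, 99.9% and 100% of peaks, within a tolerance of 0.0051. The lowest score was 22, 29 and 32 steps. This is the form a scaled read pile-up would take, and if the steps came from scaling to a common total the guide libraries would be 1.29 and 1.38 times as deep as control, but no label states this and the depth is treated as unknown. The names the authors gave the lists include the word norm and a mark that reads like a q-value threshold; neither is explained in the sources used here, so a scaling to a common depth and a threshold on q are possible but not established. Scores were used only to rank or filter peaks within a list, never to compare libraries. A further column was 0 for every peak and was not used.

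Overlaps were computed with bedtools 2.31.1 and required at least 1 bp. Peaks of all lists were merged where they overlapped or touched, and each of the 21208 regions was classed by the libraries with a peak in it. Regions that set control apart (control alone, or both guides without control) were counted beside those that set guide 1 or guide 2 apart. Random overlap came from 100 seeded placements of each guide peak on its own chromosome, among chromosomes 1 to 22 and X, with the highest coordinate seen taken as the chromosome end. Because both guides are compared with the same control, the overlap of the peaks absent from each was set against the product of their rates and against 100 draws in which each guide missed control peaks at its rate in each of 10 bins of control score.

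Genes came from the RefSeq annotation of assembly GRCh38, which has the coordinates of hg38, with 1 span per gene and without strand, exons or transcription start sites. In place of start sites, a gene was counted as marked when a peak lay within 10 kb of either end of its span. A peak or region was near a gene end when its midpoint lay within 1 kb of an end of a protein-coding gene, and otherwise inside or outside gene spans; exons, introns and untranslated regions were not told apart. The 9 gene lists held 264 entries, all of which matched the annotation: interferon response, NF-kB, cell death, TGF-beta and Smad targets, AP-1 and immediate early, Hippo and YAP targets, housekeeping, and hepatocyte and lymphocyte genes as lists that should be silent in this line. Each list was set against 10000 random lists of protein-coding genes matched on 10 groups of gene length. The percentile is a description of these libraries, not a p-value. The random lists were not matched on whether genes are active in this line. Several members of a list can share 1 peak where genes lie close together, and paralogs such as the IFIT genes can share reads.

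The design, gene lists, rule for named genes and alternatives were fixed before the data were examined. Named were SMAD3 and IRF3, up to 4 members of each list marked in all libraries, in control alone or in both guides alone, by highest control score (guide 1 where control had no peak), and the closest gene within 50 kb of the 10 highest-scoring peaks in regions of all libraries, of control alone and of both guides alone. Some genes that this rule names are not reported here. Alternatives were a reciprocal overlap of 50%, peaks within 500 bp counted as overlapping, peaks at or above the median score of their list, lists of equal length (16811 or 5000 peaks), chromosomes 1 to 22 and X only, 1 guide at a time, peaks at or above the median in the list that has them and absent from the full other lists, windows of 2 kb and 50 kb, and a limit of 3 kb for near a gene end. Added after seeing the data were leaving out ribosomal DNA and sequences other than chromosomes 1 to 22 and X, 10 kb around the whole gene span, and location at equal list lengths.

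No genome sequence was used here, so the planned search for IRF, AP-1, SMAD and other motifs, a check of base composition and the mapping of the guide target sites were not run. Shares carry Wilson 95% intervals, which cover counting error only and not variation between cultures. Overlap classes and gene links were tested on simulated data, where 100% of 5000 regions over 3 lists and 100% of 1000 genes linked to a control list were recovered. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.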

Results

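IRF3, a transcription factor that switches on interferon and antiviral genes when a cell senses viral nucleic acid, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in BT549, a basal-like human breast cancer cell line. The cells had been transfected with polyI:C, a synthetic double-stranded RNA that mimics viral infection. They expressed Cas9 together with a control guide RNA or with guide 1 or guide 2 against SMAD3, a transcription factor of the TGF-beta pathway. The comparison asks which IRF3 binding regions differ when the Smad3 gene is inactivated. Each of the 3 groups held 1 library, so no difference had a replicate check, no test between groups was made, and peaks and genes were not treated as replicates. The titles of both Smad3 guide samples name the cells BT549-caSmad3, whereas the control title names BT549, so a difference in parent line between control and guides was not excluded.

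The control list held 18028 peaks with a median width of 396 bp, the guide 1 list 16811 peaks with a median of 406 bp, and the guide 2 list 19609 peaks with a median of 424 bp. The peaks covered 8.29 Mb, 7.75 Mb and 9.49 Mb of the hg38 genome. The files gave no read counts, so the depth of each library was unknown, and the length of a peak list depends on depth. All intervals below are Wilson 95% intervals and cover counting error only.

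At SMAD3 itself (chromosome 15, 67065602 to 67195169), no list had an IRF3 peak within 10 kb of either end of the gene. Each list had 1 weak peak inside the gene span. The control peak at 67150390 to 67150737 was absent from both guide lists and had an authors' score of 21.2, where the control median was 40.42. The guide peaks overlapped each other at 67105377 to 67105731 in guide 1 and 67105359 to 67105652 in guide 2, and scored above 8.93% and 17.5% of their lists. At IRF3 (chromosome 19, 49659572 to 49665857), all 3 lists had 2 peaks, and the stronger control peak (49665542 to 49666261) lay at the gene end and scored above 83.6% of the list. IRF3 peaks do not measure whether SMAD3 was inactivated, so these values do not check the guide labels.

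Most regions with a peak in the anti-IRF3 libraries were shared by control and both Smad3 guides. They included regions at the antiviral genes IFIT2, ISG15, IFI6 and RIGI, the chemokine genes CXCL1, CXCL2 and CXCL8, and the TGF-beta target genes ID1, ID2, ID3 and CCN1. Whether these peaks mark IRF3 binding or signal at active genes in general was not settled. Of the control peaks, 84.0% (83.4 to 84.5) overlapped a guide 1 peak and 91.4% (90.9 to 91.8) overlapped a guide 2 peak. Merging the peaks of all lists gave 21208 regions, of which 14404 (67.9%) held a peak in all 3 libraries. In the control list 1209 peaks, or 6.71% (6.35 to 7.08), were absent from both guide lists, and 1198 regions held a peak in both guides but none in control. Random placement of the guide peaks on their chromosomes gave a mean of 107 overlapping control peaks for guide 1 (82 to 130 in 100 draws) against 15098 observed, and 127 for guide 2 (100 to 159) against 16431 observed. Keeping each placed peak within or beyond 10 kb of a protein-coding gene end, as its original was, raised the random means to 245.5 and 279.8. This limit of 10 kb is wider than the 1 kb used for near a gene end elsewhere. Random placement ignores open chromatin, so these means give only a floor for the overlap.

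The peaks that set control and guides apart were weak ones. Among the 3606 control peaks with the lowest authors' scores, 20.5% (19.2 to 21.9) were absent from both guides, against 0.582% (0.381 to 0.889) of the 3606 with the highest. Only 64 of the 1209 control-only peaks, 5.29% (4.17 to 6.70), scored at or above the median of the control list. Among the guide 1 peaks in regions held by both guides and not by control, 67 of 1200, 5.58% (4.42 to 7.03), scored at or above the guide 1 median. Control peaks absent from guide 1 numbered 2892 and from guide 2 1558. Independent lists of those sizes would share 250 and draws matched on control score shared a mean of 538 (483 to 582 in 100 draws), against the 1209 observed. Both comparisons use the same single control library, so part or all of that excess may come from the shared control. It does not show that the guides agree, and it was not particular to control. Of the guide 1 peaks, 1624 overlapped no control peak and 722 no guide 2 peak, and guide 1 alone held 363 regions. Of the guide 2 peaks, 3360 overlapped no control peak and 3773 no guide 1 peak, and guide 2 alone held 2134 regions. Those region counts were also above the product of the rates.

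The highest-scoring control-only peaks lay mostly in ribosomal DNA and not at antiviral genes. The first was on chromosome 20 (28495621 to 28495834) with no protein-coding gene end within 50 kb, the second was on an unplaced sequence, and the third lay inside HFM1, a meiotic DNA helicase gene (chromosome 1, 91387140 to 91387593). Repeats and reads that map to several places were not examined at these peaks, so the third is not taken as binding at HFM1. Of the 20 highest, 17 lay in ribosomal DNA, among them a peak over the ribosomal RNA gene RNA45SN2 on chromosome 21 (8207719 to 8208267). Of the 10 highest-scoring guide 1 peaks in regions held by both guides and not by control, 3 lay inside genes: EXT1, which encodes a heparan sulfate polymerase (chromosome 8, 117831524 to 117831815), BCKDHB, of branched-chain amino acid breakdown (chromosome 6, 80457308 to 80457683), and DCLK1, a kinase gene (chromosome 13, 35994491 to 35994951). Outside protein-coding genes, 4 had CNTNAP3, LOC124904228, SARAF and TEX26 as their closest protein-coding genes, at 3251 to 41496 bp, and of these the first overlapped the pseudogene VN2R3P and the second the long non-coding RNA gene LOC124900404. The other 3 had no protein-coding gene end within 50 kb.

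**Figure D1:**
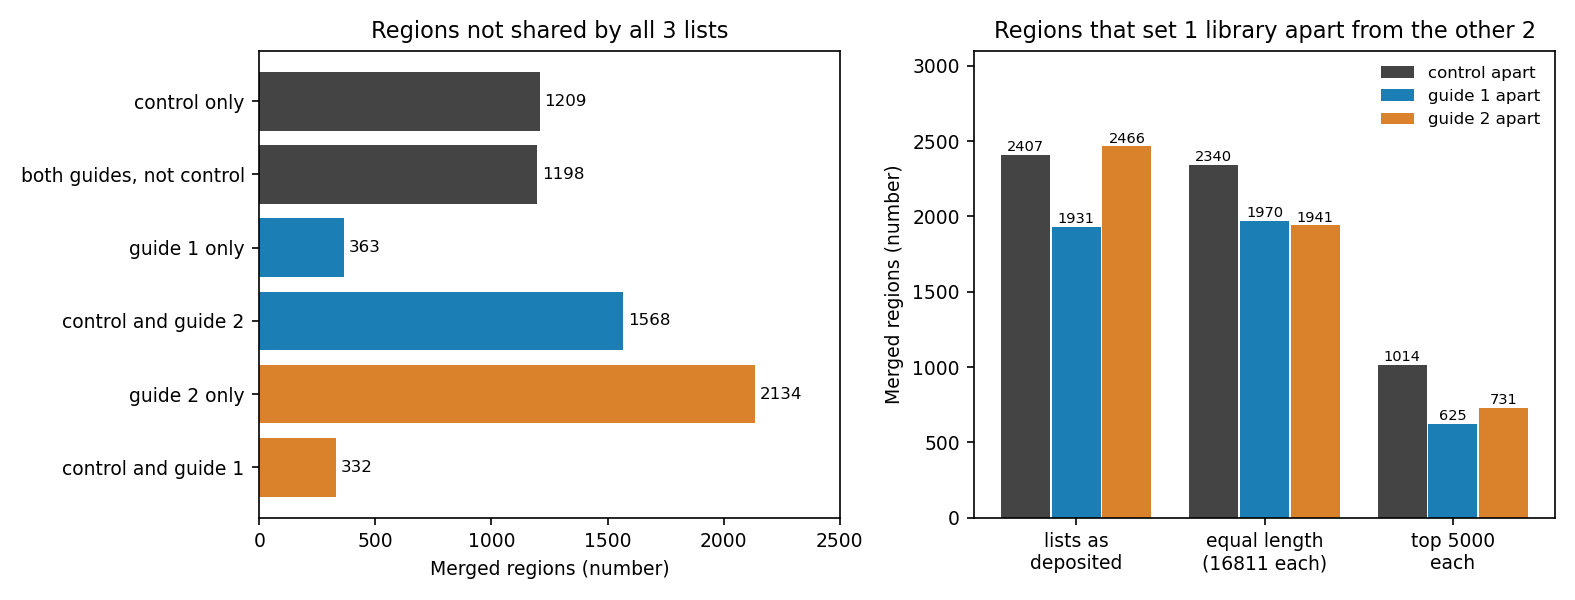
Left, the number of merged regions for each combination of libraries other than all 3, coloured by the library that the combination sets apart. Right, the number of regions that set each library apart from the other 2, for the lists as deposited (2407, 1931 and 2466), for equal-length lists and for the 5000 highest-scoring peaks of each list (1014, 625 and 731).

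Guide 2, not control, had the most regions that set it apart in the lists as deposited, where its list was also the longest. Regions found in control alone or in both guides alone came to 2407, against 2466 that set guide 2 apart and 1931 that set guide 1 apart. Of the guide 1 peaks 95.7% overlapped a guide 2 peak and 90.3% a control peak, while of the guide 2 peaks 80.8% overlapped a guide 1 peak and 82.9% a control peak. Guide 2 alone held 2134 regions and guide 1 alone 363. With lists of equal length the order changed. At 16811 peaks per list, 2340 regions set control apart, 1970 guide 1 and 1941 guide 2. With the 5000 highest-scoring peaks of each list the numbers were 1014, 625 and 731. Control had the highest number in 5 of 9 settings tried, among them reciprocal overlap on the unequal lists (3639, 2834 and 3584). Guide 2 led in the rest, none of which cut lists by score or to equal length. The 3 possible splits are too few to test the grouping against chance.

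Regions with a peak in control alone lay near gene ends more often than regions with peaks in both Smad3 guides alone. Within 1 kb of an end of a protein-coding gene lay 45.4% (42.6 to 48.2) of 1196 control-only regions on chromosomes 1 to 22 and X, and 10.1% (8.53 to 11.96) of 1196 regions of both guides. Of the latter, 50.3% (47.4 to 53.1) lay outside protein-coding genes. Regions in all 3 lists were near a gene end in 53.6% (52.8 to 54.4), those in guide 1 alone in 20.1% (16.3 to 24.5) and those in guide 2 alone in 17.3% (15.7 to 18.9). Taken as whole lists, 51.7% (51.0 to 52.5) of control peaks, 49.8% (49.0 to 50.5) of guide 1 peaks and 46.0% (45.3 to 46.7) of guide 2 peaks lay near a gene end. With 5000 peaks per list the values were 76.4% (72.6 to 79.8) for control-only regions and 27.2% (23.4 to 31.4) for regions of both guides. The intervals do not include variation between cultures, and the gene annotation used gave no strand, so a promoter was not told apart from the other end of a gene.

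**Figure D2:**
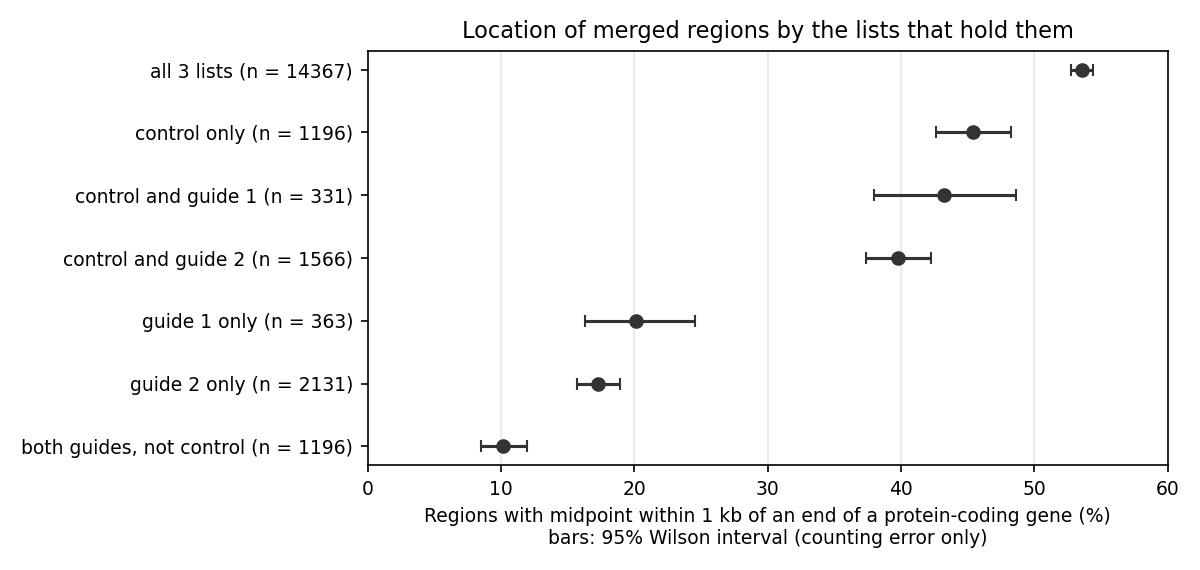
Percent of merged regions whose midpoint lay within 1 kb of an end of a protein-coding gene, by the libraries that held a peak there; points are shares, bars Wilson 95% intervals and n the number of regions on chromosomes 1 to 22 and X. Regions of both guides without control were lowest, at 10.1%, and regions of all 3 libraries highest, at 53.6%.

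Interferon-response genes carried IRF3 peaks in close to equal numbers in control and in both Smad3 guide libraries. Of 61 such genes, 38 in control, 37 in guide 1 and 37 in guide 2 had a peak within 10 kb of either gene end, and 36 had one in every library. Among them were IFI6, an interferon-induced mitochondrial protein gene (chromosome 1, strongest control peak 27671917 to 27672581), RIGI, which encodes a cytosolic sensor of viral RNA (chromosome 9, 32525255 to 32526633), IFIT2, which encodes an antiviral RNA-binding protein (chromosome 10, 89301655 to 89304678), and ISG15, a ubiquitin-like modifier gene (chromosome 1, 1012965 to 1015615). Their strongest peaks scored above 99.5%, 98.6%, 98.4% and 98.4% of the control list, above 98.7%, 98.7%, 98.1% and 98.4% of the guide 1 list, and above 99.2%, 98.9%, 99.0% and 98.7% of the guide 2 list. The exceptions were USP18, with a peak in control and guide 2, and EIF2AK2, with one in control and guide 1 (both named after their values were seen). The 23 members without a peak in any list included OAS1, OAS2, OAS3, CXCL10, MX2 and RSAD2, also chosen after their values were seen. For 7 of the 38 genes marked in control, the strongest peak within 10 kb lay closer to an end of another gene. Against 10000 random lists of protein-coding genes of like length, the interferon counts were at percentile 77.4 in control, 81.6 in guide 1 and 70.2 in guide 2.

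**Figure D3:**
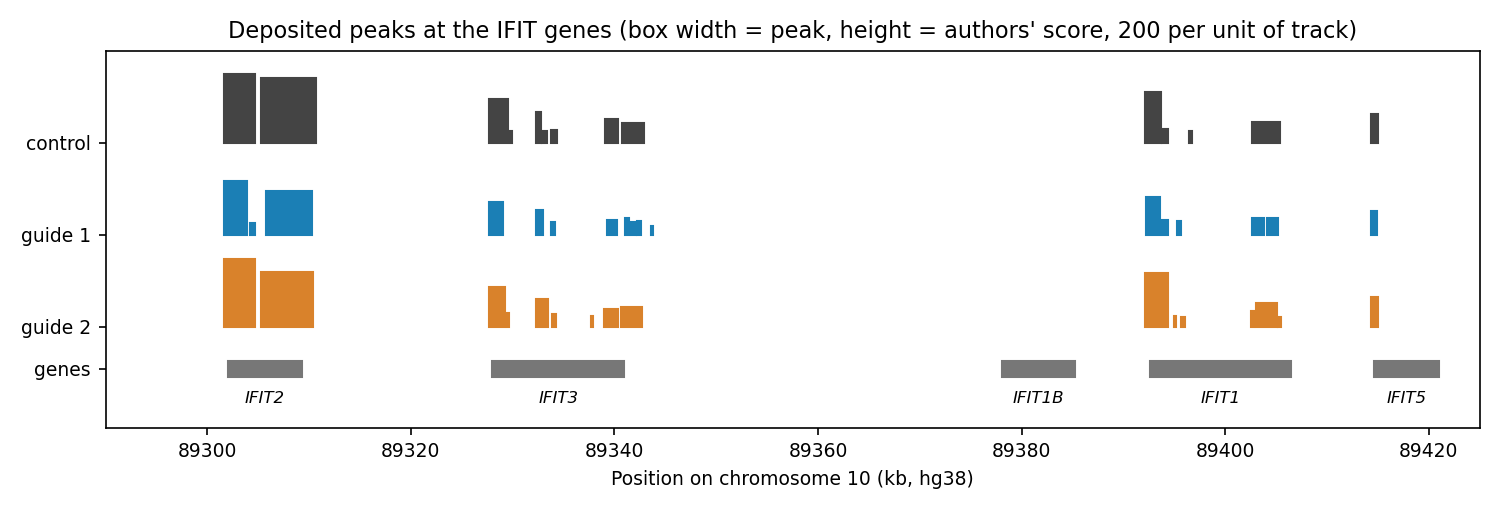
Deposited peaks over the IFIT gene cluster on chromosome 10 (position in kb, hg38) in the control, guide 1 and guide 2 libraries, each box as wide as its peak and as high as the authors' score, with gene spans below. The window held 14 control peaks over 21340 bp, 17 guide 1 peaks over 17358 bp and 16 guide 2 peaks over 21337 bp; scores are read within a library only.

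At the IFIT cluster, whose members are paralogs, IFIT2, IFIT3, IFIT1 and IFIT5 were marked in every library. Across IFIT2 the control list had 2 peaks covering 91.2% of the gene, guide 1 3 peaks covering 79.6% and guide 2 2 peaks covering 91.0%. The same stretches were divided into different numbers of peaks in different libraries.

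Genes induced through NF-kB had peaks in 20 of 25 cases in control, 18 in guide 1 and 17 in guide 2, at percentiles 99.8, 98.7 and 94.3. In control, 5 of the 20 had their strongest peak closer to an end of another gene. Peaks in every library marked CXCL1 and CXCL2, neutrophil-attracting chemokine genes, NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, and CXCL8, which encodes interleukin 8. Their strongest control peaks scored above 99.5%, 95.6%, 97.9% and 85.8% of the list. TNF was the 1 member with a peak in control alone (chromosome 6, 31580944 to 31581226, above 29.9% of the list), and that peak lay 2749 bp from TNF but 527 bp from LTB. TNFAIP3 and LIF had a peak in control and guide 1, and TRAF1 in control and guide 2, named after their values were seen. The Wilson intervals of the 3 shares were 60.9 to 91.1% in control, 52.4 to 85.7% in guide 1 and 48.4 to 82.8% in guide 2. All cover the same 25 genes, so their overlap does not test the difference. Every member marked in a guide was also marked in control.

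TGF-beta and Smad target genes were marked in 34 of 42 cases in control, 34 in guide 1 and 35 in guide 2, and PMEPA1, in guide 2, accounted for the difference. ID1, ID2 and ID3, which encode inhibitors of helix-loop-helix transcription factors, and CCN1, a matricellular protein gene, had strongest control peaks that scored above 99.6%, 97.8%, 98.6% and 98.4% of the list. The counts were at percentile 99.965 in control, 100 in guide 1 and 99.995 in guide 2. Housekeeping genes were also at percentile 100 in every library, and hepatocyte genes at 0.025 or lower. A high percentile therefore does not show binding particular to a pathway. AP-1 and immediate early genes were marked in 16 of 18 cases in every library (percentile 99.925, 99.965 and 99.95), led by the transcription factor genes JUN, MYC and JUNB and the immediate early gene IER2. The strongest JUNB peak, which covered the whole gene, had its midpoint closer to an end of HOOK2 (419 bp) than of JUNB (546 bp). With only peaks at or above the median score of each list, the TGF-beta count was 21 in control, 21 in guide 1 and 24 in guide 2.

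Cell death genes were marked in 21 of 32 cases in control, 20 in guide 1 and 21 in guide 2, at percentiles 67.2, 66.5 and 69.2. MCL1, which encodes an anti-apoptotic protein, TNFRSF10B, a TRAIL receptor gene, and BBC3, which encodes the pro-apoptotic protein PUMA, had peaks in all libraries, and the strongest control peaks scored above 99.2%, 94.4% and 91.6% of the list. The strongest peak within 10 kb of the pro-apoptotic gene BAX lay 118 bp from an end of FTL, the ferritin light chain gene. Hippo and YAP target genes were marked in 10 of 14 cases in control, 9 in guide 1 and 10 in guide 2 (percentile 92.5, 87.1 and 92.7), with peaks at GADD45B, AJUBA and AMOTL2 in every library. The strongest peak near another member, ARHGEF17, lay 51 bp from an end of RELT.

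Housekeeping genes were marked more often than interferon genes, in 23 of 24 cases in each library, or 95.8% (79.8 to 99.3), against 62.3% (49.7 to 73.4) of interferon genes in control. EEF1A1, a translation elongation factor gene, POLR2A, the gene of the largest RNA polymerase II subunit, and EIF4A1, an RNA helicase gene, had strongest control peaks that scored above 99.7%, 99.7% and 99.2% of the list. The POLR2A peak lay 159 bp from an end of that gene and 42 bp from an end of ZBTB4. Of all 19974 protein-coding genes, 56.5% had a peak within 10 kb of an end in control, 53.6% in guide 1 and 56.2% in guide 2. Libraries without polyI:C, without antibody or with another antibody were not analysed here.

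Liver and lymphoid genes were marked less often than random genes at the 10 kb window. Of 24 hepatocyte genes, 5 in control, 4 in guide 1 and 5 in guide 2 had a peak within 10 kb, and of 24 lymphocyte genes 5, 5 and 6, where random lists had medians of 13 or 14. These counts depend on the window: at 2 kb they were 3, 2 and 3 for hepatocyte genes and 0 in each library for lymphocyte genes, and at 50 kb 15, 15 and 16 and 13, 12 and 13. ITIH1, TF, APOC3 and APOA1 were the hepatocyte genes with peaks in every library, and the ITIH1 peak lay 72 bp from an end of NEK4. APOC3 and APOA1 were marked by the same peak, in control 217 bp from an end of APOA1 and 2896 bp from APOC3. The lymphocyte genes marked in control included LCK, CD3G and CD79A, and each of these had another gene closer to its strongest peak, for example HDAC1 beside LCK and UBE4A beside CD3G.

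**Figure D4:**
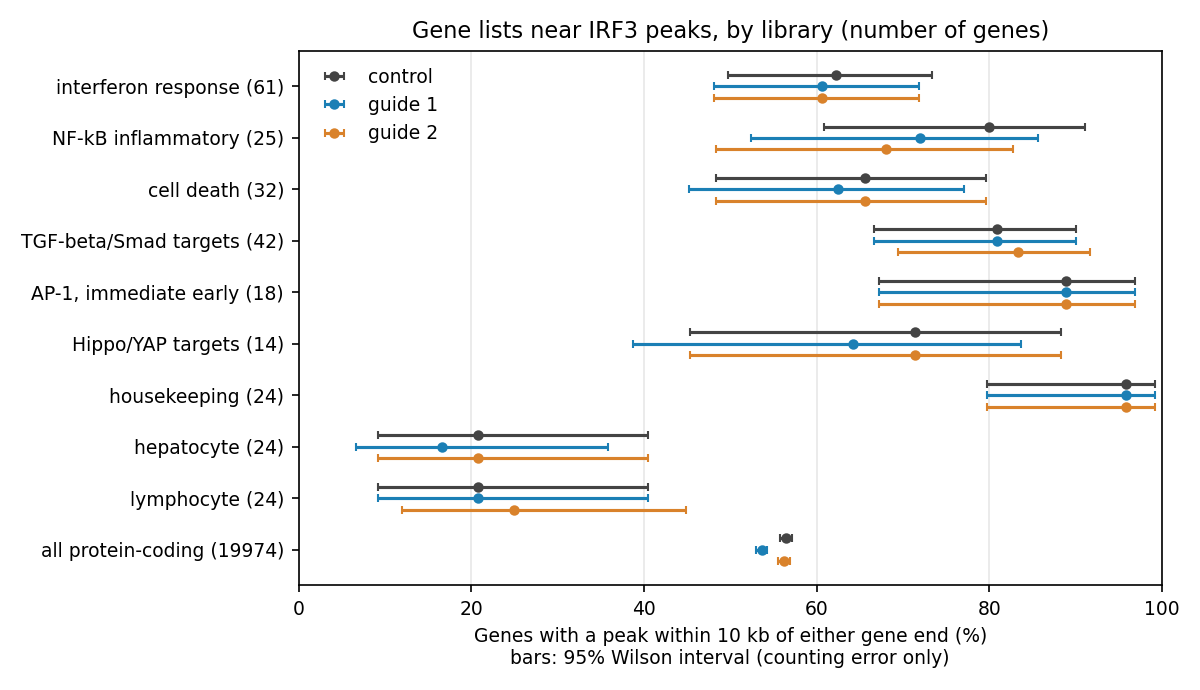
Percent of the genes in each list (number of genes in brackets) with a peak within 10 kb of either gene end in the control, guide 1 and guide 2 libraries; points are shares and bars Wilson 95% intervals for counting error. Housekeeping genes were at 95.8% in each library and the interferon list at 62.3%, 60.7% and 60.7%.

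Among the regions held by all 3 libraries, the strongest control peaks marked replication-dependent histone genes. Those at H4C15, H4C14, H4C12 and H4C11, which encode histone H4, were the highest-scoring (chromosome 1, 149859996 to 149862053 and 149831829 to 149833750, and chromosome 6, 27830678 to 27831900 and 27823744 to 27825069). The next 2 covered the small nucleolar RNA genes SNORD3B-1 and SNORD3A on chromosome 17, followed by peaks at H3C15, H3C2 and H4C8 and over the small nuclear RNA gene LOC124904138.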

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

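The ribosomal DNA counts given here were chosen after the result was seen, and no test was run in this part.

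The guide lists differed from the control list in opposite directions. The guide 1 list minus the control list was -1217 peaks, whereas the guide 2 list had 1581 more peaks than control. That difference between guides was not tested, since each group held 1 library.

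IRF3 peaks also lay on 2 unplaced sequences that hold ribosomal DNA, 41 in control, 31 in guide 1 and 32 in guide 2, outside the chromosomes used for gene comparisons. With the ribosomal DNA of chromosome 21 and elsewhere included the counts were 73, 61 and 58. Among the 100 highest-scoring peaks of each list, 5 in control (5.00%, 2.15 to 11.2) and 0 in each guide lay in ribosomal DNA, and the count of 0 of 100 has an upper Wilson bound of 3.70%.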

How the results depend on the processing

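Location at equal list lengths, the whole gene span and leaving out ribosomal DNA were chosen after the data were seen. Of the comparisons that carry the report, 59 values under an alternative stayed within 1.5 times the count or inside the interval, and 32 did not. Stricter or shorter lists hold fewer peaks, which can lower a count but need not. Control peaks absent from both guides numbered 1220 with 16811 peaks per list, against 1209 as deposited. Counts under different cuts are not shares of the same list, and the causes of the changes were not tested. Control peaks absent from both guides numbered 1989 with reciprocal overlap, 771 with peaks at or above the median score, 543 with 5000 peaks per list, 64 with stronger peaks set against full lists, and 2892 against guide 1 alone. Regions of both guides without control numbered 471 with 5000 peaks per list and 43 with stronger peaks set against full lists. With guide 1 left out of the comparison, 3332 regions of guide 2 had no control peak. Regions setting control apart came to 3639 (reciprocal), 1570 (median score), 1014 (5000 peaks) and 107 (stronger peaks against full lists), those setting guide 1 apart to 1082, 625 and 64, and those setting guide 2 apart to 1363, 731 and 83 in the last 3 settings. TGF-beta targets with a peak at or above the median score numbered 21 in control and 21 in guide 1. Control-only regions were near a gene end in 54.3% (3 kb limit), 67.9% (median score) and 76.4% (5000 peaks), regions of both guides in 14.5%, 16.1% and 27.2%, and regions of all 3 lists in 58.2%, 67.9% and 75.3%, with 55.4% at equal lengths, so control-only regions stayed above those of both guides in each setting. Random placement that kept each peak within or beyond 10 kb of a gene end gave 245.5 and 279.8. Of the other values 87 stayed and 24 did not: 6 lower at 2 kb and 6 higher at 50 kb, all of them hepatocyte or lymphocyte counts, 3 higher at 3 kb, and 3 higher and 6 lower at the median score. The motif alternatives were not run, for want of a genome sequence here. No paired analysis was possible because each group held 1 library. Unknown depth limits every count of absent peaks, most of which were weak.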

Other observations

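The tests on housekeeping genes and on gene density, and the settings with 5000 peaks per list for location and with ribosomal DNA left out, were chosen only after the result was seen, as were the counts of histone and small RNA genes and of list genes by class of region.

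Histone and small RNA genes made up most of the top of every list. Of the 100 highest-scoring peaks, 35 in control, 37 in guide 1 and 36 in guide 2 lay within 500 bp of a histone gene, against 0.266%, 0.291% and 0.250% of all peaks. A further 30, 31 and 30 lay as close to small nuclear or small nucleolar RNA genes. Of 69 replication-dependent histone genes, 62 in control, 61 in guide 1 and 61 in guide 2 had a peak within 500 bp. The control share of 89.9% lay inside the interval of the guides (88.4%, 78.8 to 94.0).

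Some TGF-beta target genes lay near regions found in the Smad3 guide libraries and not in control. A region of both guides without control lay near 4 such genes, among them CCN2, SMURF2 and ITGB6, against a median of 2 genes in random lists matched on the number of regions near each gene (percentile 92.9), and against a matched median of 1 once peaks within 500 bp were merged (4 genes, percentile 97.0). The CCN2 region (chromosome 6, 131938076 to 131938476) lay 9900 bp from the gene and scored above 45.4% of the guide 1 list. Regions in guide 2 alone lay near 9 TGF-beta targets, among them SMAD6, TGFBI and PMEPA1, against a matched median of 4 (percentile 98.7), and near 4 with a percentile of 74.9 once peaks within 500 bp were merged. Such guide 2 regions were not particular to TGF-beta targets: they lay near 7 AP-1 and immediate early genes (matched median 4, percentile 96.0, and 97.6 after merging), 3 Hippo and YAP targets (median 1, percentile 91.9, and 97.6 after merging) and 6 housekeeping genes (median 4, percentile 90.2, and 70.6 after merging). BHLHE40, a TGF-beta target chosen after its values were seen, had the strongest control-only region near any gene of the interferon and TGF-beta lists (chromosome 3, 4979476 to 4979703, above 65.2% of the control list), and this region joined a shared one once peaks within 500 bp were merged.

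Control-only regions lay near 10 of the 61 interferon genes (among them IFNB1, IFIT1, IFIT3, OASL, CCL5 and RIGI), against a median of 3 in random lists (percentile 99.9). IFIT1 and IFIT3 also lay near regions of guide 1 alone and near regions of guide 2 alone. Lists matched on the number of regions near each gene left the count at percentile 98.0, and 2.99% of those lists reached it. That percentile is a description and 1 of many computed over lists and classes of region. A mere surplus of regions near these genes was therefore not excluded. With peaks within 500 bp merged, 4 genes (OASL, RIGI, IRF2 and TRIM25) had such a region, at percentile 68.3, so small control peaks split off beside peaks shared with the guides may account for the excess. The 11 regions were weak, with scores of 19.22 to 28.49 where the control median was 40.42. A weaker spread of IRF3 around these genes after Smad3 inactivation stays open and was not tested, since each group held 1 library.

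Control-only regions lay nearer gene ends than regions of both guides, and lists of different lengths do not account for it, since with 5000 peaks per list the difference was 49.2 percentage points. A difference in base composition between libraries, which was not measured, may account for part of this nearness to gene ends. Outside genes, control-only regions made up 23.7% (19.3 to 28.8) of the 304 control-only or both-guide regions with the lowest gene density. Of the 305 with the highest density they made up 50.2% (44.6 to 55.7), a difference of 26.5 points. Near gene ends no such gradient was seen (79.6%, 84.6% and 81.1% from low to high density). The lowest of these shares (79.6%, 73.8 to 84.4) was above the 50.2% at the highest density outside genes. Gene density thus left a contrast between near and outside in place. Gene density stands in for base composition only in part, because no genome sequence was used. A shift of IRF3 towards sites away from genes after Smad3 inactivation, and a difference between BT549 and BT549-caSmad3 cells, stay open as untested hypotheses.

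Peaks at genes with no known IRF3 role may reflect signal at active genes in general, whatever the antibody target. In control 95.8% (79.8 to 99.3) of the 24 housekeeping genes had a peak within 10 kb, above the 62.3% (49.7 to 73.4) of interferon genes, while 20.8% (9.24 to 40.5) of hepatocyte genes had one. A true presence of IRF3 at these genes after polyI:C stays open, because libraries without polyI:C or with another antibody were not analysed here.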
